A study of Arabidopsis thaliana with 18 samples.

How the data were processed

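Total RNA from whole 5-week-old rosettes of Arabidopsis thaliana Columbia-0 was labelled with biotin and hybridised to 1-colour Affymetrix Arabidopsis Genome arrays, with 1 array per sample. The 18 arrays fell into 6 groups of 3, formed by 3 genotypes and 2 oxygen levels. The genotypes were the wild type, a line carrying 35S::HA::RAP2.12 (HA-RAP2.12) and a line carrying 35S::amiRAP2.2-12, an artificial microRNA (amiRAP2.2-12). Plants were kept in the dark at 22 °C for 1.5 h at 21% oxygen (called air here) or 1% oxygen (hypoxia). Groups and replicate numbers were taken from the sample labels. The labels do not say whether the replicates were separate plants, so every p-value measures only the spread between these samples.

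The values deposited by the authors were on the log2 scale, 1 value per probe set and array, produced by GCRMA per the submitters' processing notes, which give no version. GCRMA corrects the background, equalises the distribution between arrays and summarises each probe set. The table held 22810 probe sets. After 64 control probe sets were left out, 22746 were tested. The lowest value was 2.11 on every array, and 35.4% of all values lay under log2 2.5, a limit chosen after the data were examined and used here to call a group with a mean under it "at the floor". Differences against a group at the floor depend on how the background was removed. Array data carry no read depth, and the number of arrays limits the precision.

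The annotation used here listed 14016 of the tested probe sets. Of these, 13513 named 1 gene and 503 named several. Current symbols came from a gene table of the assembly TAIR10.1 for 13436 of the 13513, and 77 kept the name in the annotation. The other 8730 probe sets (38.4%) were not listed. Probe sets for the genes targeted by the constructs were not among the named ones, so the levels of RAP2.12 and RAP2.2 were not analysed here.

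Group means were fitted to all 18 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with its default prior). Each of 9 comparisons was tested two-sided, with Benjamini-Hochberg adjustment over all 22746 probe sets and a threshold of 0.05, without a filter on dim probe sets and without a replicate block. The comparisons were hypoxia against air in each genotype, each transgenic line against wild type in air and under hypoxia, and the difference between each line's hypoxia response and that of wild type (the interaction). Changes are given as log2 differences with the standard error of the fit (SE), and levels as the mean ± SD of 3 arrays. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

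Gene lists were written from general knowledge. Of 19 lists with 324 loci, 72 loci had a named probe set, and 9 lists with at least 3 such members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists within a comparison. Each list gene was represented by the probe set with the highest mean. Members past the threshold were counted over all probe sets and again adjusted over the list alone. Each list test was repeated with an estimated correlation between members, and no list call in any of the 9 comparisons held with it. A further set was chosen without the tested arrays: probe sets raised, or lowered, at least 2-fold (log2 1) at adjusted p under 0.05 by hypoxia in a fit of the 6 arrays of 1 genotype were tested for differences between the other genotypes in a fit of the other 12 arrays.

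The genes named in the text follow a rule. In each comparison these were the 5 largest rises and 5 largest falls among probe sets of 1 named gene past the threshold, with no overlap between the arrays of the groups compared, together with up to 4 members per list with the smallest adjusted p. A set of 15 low-oxygen and targeted genes was to be named always, and 1 of them, HRA1 (AT3G10040), had a named probe set. The comparisons, tests, lists, this rule and the alternatives listed below, except where stated, were fixed before the data were examined. Any gene or probe set outside the rule is described as chosen after its values were seen.

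The alternatives tried were quantile normalization of the deposited values, centring of each array on the common median, a filter keeping the 13697 probe sets above log2 4 on at least 3 arrays, removal of 1061 probe sets with identifiers ending in _s_at or _x_at, eBayes with trend and robust options, limma's arrayWeights, a fit of only the arrays compared, the replicate number as a block, a log2 change of at least 1, the mean of all probe sets per gene, an estimated correlation, other limits for the chosen sets, and leaving out each array in turn. Leaving out 4 arrays that deviated together was added after the data were seen, as were sets of genes sharing a symbol prefix (at least 8 probe sets).

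The fit was tested on simulated data with 22746 probe sets, of which 200 were changed. For the wild type hypoxia response it recovered 16.4% of changes of log2 0.5, 76.1% of log2 1 and 98.5% of log2 2, with 7.30% of calls false. For HA-RAP2.12 against wild type in air the shares were 34.3%, 80.6% and 90.9%, with 3.52% false. For the HA-RAP2.12 interaction they were 14.9%, 58.2% and 81.8%, with 7.21% false. Changes were placed only in probe sets with a wild type air mean above log2 6. The simulated noise was normal, independent between arrays and of the same spread in all groups. The real groups differed in spread and some arrays deviated together, so these shares may not hold for the real data.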

Results

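Transcript levels were measured on 18 arrays of whole rosettes, with 3 arrays for each combination of 3 genotypes and 2 oxygen levels. RAP2.12 and RAP2.2 are ethylene response factors of group VII, a group known to activate genes under low oxygen. The series asks how altering RAP2.12 affects expression in air and under hypoxia. Oxygen level was the main axis of the data: the first principal component of the 10988 probe sets with a mean above log2 6 held 63.1% of their variance, and the second 11.2%. The median SD between replicates was 0.104 in wild type air and 0.110 in wild type hypoxia, 0.137 and 0.122 in HA-RAP2.12, and 0.151 and 0.223 in amiRAP2.2-12, on the log2 scale.

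In wild type rosettes, 1.5 h at 1% oxygen raised a set of strongly induced genes from near the background. AT4G10270, a gene of the wound-responsive family, rose from 3.33 ± 0.10 to 14.00 ± 0.07 (SD, n = 3), a log2 change of 10.68 (SE 0.37). HRA1 (AT3G10040), a transcription factor known to restrain RAP2.12, rose by 8.48 (SE 0.33), AT4G33560 by 9.03 (SE 0.55), AT2G17850 by 8.76 (SE 0.81) and AT5G66985 by 7.66 (SE 0.58), the last 2 from a wild type air level at the floor. The largest falls among named genes were in EXLA1, an expansin-like gene (-4.92, SE 0.29), AT2G41990 (-4.41, SE 0.30), AT4G29780 (-4.24, SE 0.63), AT4G37220 (-4.17, SE 0.39) and EXO, a gene linked to cell expansion (-3.99, SE 0.37). In total 2608 probe sets rose and 2343 fell, and 1608 of these 4951 changed at least 2-fold.

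Of 27 measured genes on the list of low-oxygen induced genes, 25 rose in wild type, by the count over all probe sets and adjusted over the list alone, and none fell. Examples beside those above are AT1G33055 (7.12, SE 0.24) and AT3G27220 (6.84, SE 0.31), and the median change of the list was 4.30 (camera adjusted p = 4.30e-25, and adjusted p = 0.0762 with an estimated correlation). Among 4 fermentation and sucrose breakdown genes, PDC2, a pyruvate decarboxylase, rose by 2.17 (SE 0.30), AT4G17260, a lactate dehydrogenase, rose by 1.54 (SE 0.21), and PPDK, pyruvate orthophosphate dikinase, fell by 1.50 (SE 0.25), with no call for the list (adjusted p = 0.729). Heat shock genes rose in 3 of 6 cases (4 adjusted over the list alone), among them AT5G48570, a peptidyl-prolyl isomerase (6.04, SE 0.47), and the small heat shock protein gene AT1G53540 (4.60, SE 0.72, from the floor), with a list median of 2.40 (adjusted p = 0.0129, and adjusted p = 0.326 with an estimated correlation). Of these 6, ATHSP22.0 and AT1G52560 were at the floor in every group, which limits this list in all comparisons. Photosynthesis genes moved by small amounts: 2 of 5 fell over all probe sets and 4 adjusted over the list alone, including SBPASE (-0.34, SE 0.05) and PRK (-0.50, SE 0.11), both enzymes of the Calvin cycle. Their list median of -0.14 gave adjusted p = 0.0428, but 0.201 after quantile normalization, 0.133 after median centring, 0.323 with the filter on dim probe sets, 0.0651 with only the arrays compared and 0.355 as adjusted p with an estimated correlation. The call was also lost without wild type air replicate 1 (0.0758) or 2 (0.0573), wild type hypoxia replicate 3 (0.0990), HA-RAP2.12 air replicate 1 (0.0508) or amiRAP2.2-12 hypoxia replicate 1 (0.0528).

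The remaining lists gave no call in wild type. WRKY6 rose by 1.72 (SE 0.39) among 4 rapid stress genes (adjusted p = 0.776), AT2G41730 fell by 1.19 (SE 0.34) among 5 mitochondrial dysfunction genes (0.847), and MCCA, a subunit of methylcrotonyl-CoA carboxylase, fell by 0.82 (SE 0.11) among 3 dark and sugar starvation genes (0.729). Of the 4 rapid stress genes, GSTU25 was at the floor in every group. COR47, a dehydrin, rose by 0.93 (SE 0.25) among 3 abscisic acid and cold genes (0.776), and 0 of 6 cytosolic ribosomal protein genes passed (0.776). Lists with fewer than 3 measured members were not tested as lists. Within these, RTE1, a regulator of ethylene receptors, rose by 0.29 (SE 0.07) while EIN3 did not pass (0.16, SE 0.13), the expansin EXPA8 rose by 1.89 (SE 0.29) while EXPA4 did not pass (0.07, SE 0.48), and the glutaredoxin GRX480 of the salicylic acid list rose by 4.16 (SE 0.54). The clock gene GI (-0.03, SE 0.10) and the jasmonate genes PDF1.2 (0.61, SE 0.81) and THI2.1 (at the floor) did not pass. The root marker genes PYK10 (0.76, SE 0.91) and AT4G11290 (0.33, SE 0.15, at the floor) did not pass either, and no flower, seed or senescence marker had a named probe set.

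**Figure D1:**
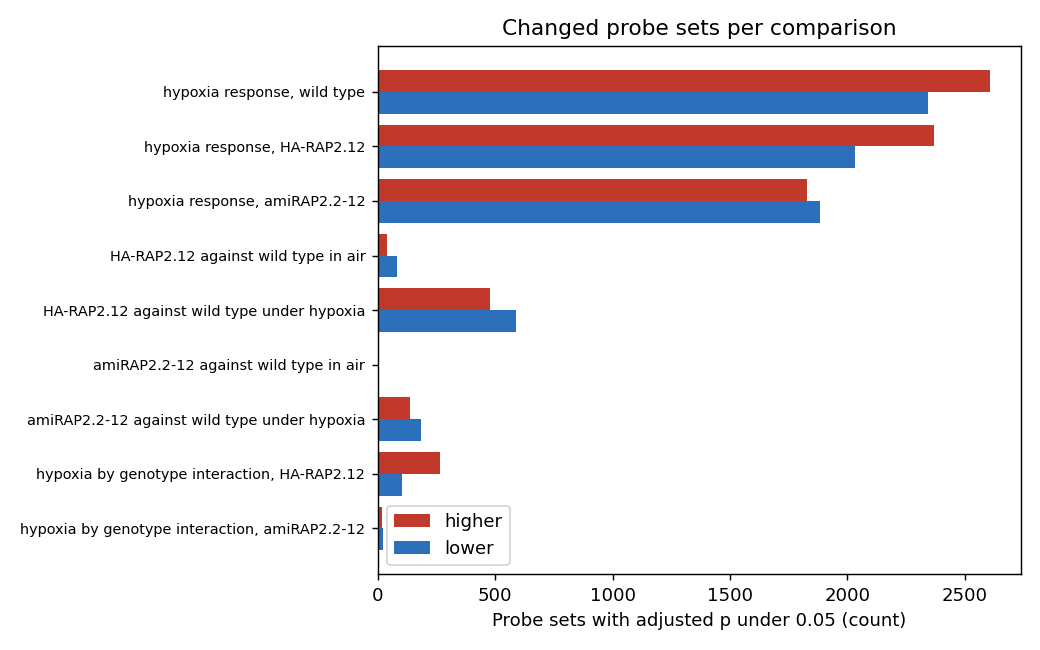
Number of probe sets with adjusted p under 0.05 (horizontal axis, from 0) in each of the 9 comparisons, with higher and lower probe sets as separate bars. The wild type response to hypoxia held 2608 higher and 2343 lower probe sets, and amiRAP2.2-12 against wild type in air held 2 and 1.

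Both transgenic lines also responded strongly to hypoxia. In HA-RAP2.12, IAGLU, an indole-3-acetate glucosyltransferase, rose by 6.52 (SE 0.25), AT4G28140 by 6.34 (SE 0.30), AT4G33560 by 6.26 (SE 0.55) and HRA1 by 5.74 (SE 0.33), while GAT1_2.1 (-5.73, SE 0.63) and EXLA1 (-4.98, SE 0.29) fell. In amiRAP2.2-12, AT4G10270 rose by 9.21 (SE 0.37), AT4G33560 by 7.37 (SE 0.55, from the floor), HRA1 by 7.08 (SE 0.33) and IAGLU by 6.19 (SE 0.25), while GAT1_2.1 (-6.53, SE 0.63) and AT2G38240 (-5.37, SE 1.31) fell. HA-RAP2.12 gave 2369 higher and 2035 lower probe sets, and amiRAP2.2-12 gave 1829 and 1882. Across all 3 genotypes, 1086 probe sets were higher and 1115 lower under hypoxia in every one. Over the 10988 brighter probe sets, which are not independent replicates, the wild type response correlated with that of HA-RAP2.12 at r = 0.783 and with that of amiRAP2.2-12 at r = 0.842, and the responses of the transgenic lines correlated at r = 0.848.

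By list, 22 of 27 low-oxygen genes rose in HA-RAP2.12 (25 adjusted over the list alone; median 2.53; adjusted p = 0.173 with an estimated correlation) and 21 in amiRAP2.2-12 (23 adjusted over the list alone; median 2.60; adjusted p = 0.119 with an estimated correlation). Rapid stress genes rose in 3 of 4 cases in HA-RAP2.12, also adjusted over the list alone, namely WRKY6 (2.39, SE 0.39), WRKY53 (1.99, SE 0.31) and the zinc finger gene STZ (1.84, SE 0.40), with adjusted p = 0.00423 for the list and adjusted p = 0.201 with an estimated correlation. Heat shock genes rose in 3 of 6 cases in amiRAP2.2-12, also adjusted over the list alone, including AT5G48570 (4.53, SE 0.47), with adjusted p = 0.0234 for the list, 0.0539 after median centring, 0.0607 with only the arrays compared and adjusted p = 0.405 with an estimated correlation. PDC2 rose in both lines, by 1.65 (SE 0.30) in HA-RAP2.12 and 1.16 (SE 0.30) in amiRAP2.2-12. The count in amiRAP2.2-12 was 642 rather than 3711 when only the 6 arrays of that line were fitted, and the share of its calls that were higher was 49.3% with the deposited values and 63.2% after median centring, which shifted array medians by up to 0.142. In HA-RAP2.12 the share was 53.8%, and 49.2% after quantile normalization.

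In air, HA-RAP2.12 rosettes already held raised levels of several genes that hypoxia induces. AT4G10270 was at 8.18 ± 0.29 (n = 3) against 3.33 ± 0.10 (n = 3) in wild type, a difference of 4.85 (SE 0.37). AT5G66985 (4.43, SE 0.58) and AT2G17850 (4.40, SE 0.81), both at the floor in wild type, AT1G33055 (3.27, SE 0.24), AT4G39675 (2.87, SE 0.52) and AT3G03270, a universal stress protein gene (2.71, SE 0.34), were higher as well. HRA1 was higher by 1.74 (SE 0.33, adjusted p = 0.0404). The lower genes included AT4G29780 (-3.65, SE 0.63), AT2G32030 (-2.48, SE 0.47), AT5G25100 (-2.37, SE 0.14), AT1G72920 (-2.29, SE 0.42) and AT3G04640 (-2.27, SE 0.35). Among the probe sets without a gene name, the most raised differed by 9.73 (SE 1.21) from a wild type level at the floor and the most lowered by -3.68 (SE 0.40) to a level at the floor, both chosen after their values were seen.

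Of the low-oxygen list, 7 of 27 members were higher in HA-RAP2.12 in air and none lower, and adjusted over the list alone 12 were higher and 1 lower. The list mean was 7.20 ± 0.18 (n = 3) against 6.01 ± 0.02 (n = 3) in wild type, and the median difference was 0.56 (adjusted p = 5.88e-10, and adjusted p = 0.405 with an estimated correlation). No rapid stress gene passed over all probe sets and 2 of 4 were lower adjusted over the list alone, with STZ at -1.70 (SE 0.40) and WRKY53 at -1.04 (SE 0.31). The list was lower (adjusted p = 0.0366, and adjusted p = 0.405 with an estimated correlation). That call was lost without wild type air replicate 1 (0.0576) or 2 (0.102) or HA-RAP2.12 air replicate 3 (0.0843). The other 7 lists tested gave no call in the main fit. With arrayWeights, abscisic acid and cold genes (adjusted p = 0.0245), ribosomal protein genes (0.0261) and photosynthesis genes (0.0315) gained one. Abscisic acid and cold genes also passed after median centring (0.0446). With only the arrays compared, abscisic acid and cold genes (0.00273) and ribosomal protein genes (0.00214) passed. In total 39 probe sets were higher and 83 lower. That count of 122 ranged from 35, without wild type air replicate 3, to 343, without amiRAP2.2-12 hypoxia replicate 2, when single arrays were left out, and was 75 with the replicate number as a block, 700 with arrayWeights, 199 with the filter on dim probe sets and 617 without 4 arrays that deviated together.

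**Figure D2:**
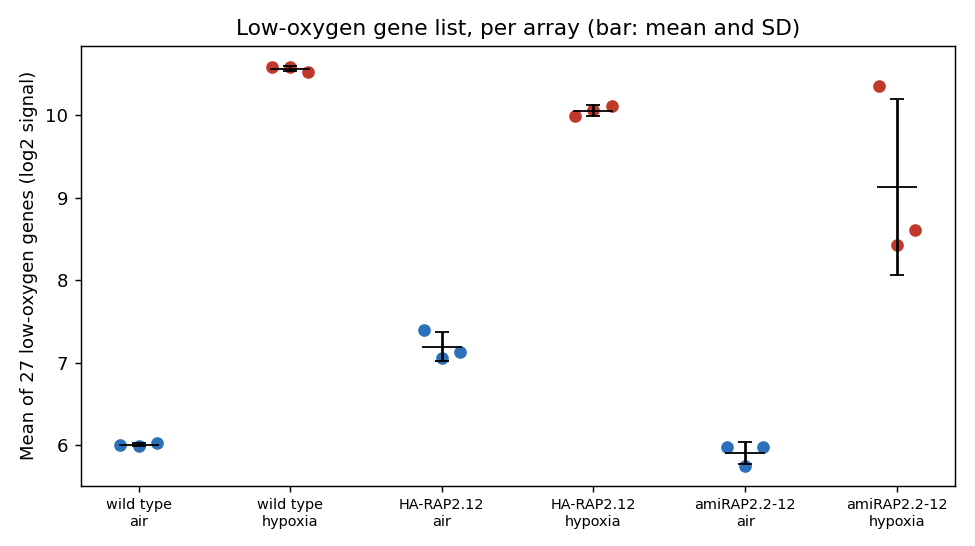
Mean log2 signal of the 27 measured low-oxygen genes on each array (points), by genotype and oxygen level, with the group mean and SD as bars. HA-RAP2.12 in air lay at 7.20 against 6.01 in wild type, and the 3 amiRAP2.2-12 hypoxia arrays ran from 8.42 to 10.36.

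Under hypoxia, the question was how HA-RAP2.12 differed from wild type once both lacked oxygen. AT5G39580 was at 6.96 ± 0.13 (n = 3) against 2.86 ± 0.03 (n = 3), a difference of 4.104 (SE 0.66). B120 (3.20, SE 0.54), XTH18, a xyloglucan endotransglucosylase/hydrolase gene (3.15, SE 0.59), AT3G01830 (2.90, SE 0.67, at the floor in wild type) and AT3G54150 (2.84, SE 0.46) were higher. AT1G53540 was lower (-4.42, SE 0.72, at the floor in HA-RAP2.12), as were the co-chaperone gene Hop3 (-3.37, SE 0.76), OSM34, an osmotin-like gene (-3.25, SE 0.72), AT5G24240 (-2.74, SE 0.23, at the floor in HA-RAP2.12) and AT1G26390 (-2.50, SE 0.30). AT5G24240 had an SD of 0 at the floor in every group but wild type hypoxia (4.85 ± 0.69, n = 3). Its SE here and in later comparisons therefore rests largely on values without spread. Of the low-oxygen list, 3 members were lower, PDC2 (-1.28, SE 0.30), AT1G74940 (-0.93, SE 0.19) and AT3G10020 (-0.36, SE 0.09, not past the threshold after quantile normalization), and adjusted over the list alone 1 was higher and 6 lower. The list median was -0.48 (adjusted p = 0.00173, and adjusted p = 0.520 with an estimated correlation), and HRA1 differed by -0.998 (SE 0.33) without passing (adjusted p = 0.117).

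Among the other lists, 1 of 6 heat shock genes was lower (2 adjusted over the list alone), with AT5G48570 at -1.71 (SE 0.47) and a list median of -0.86 (adjusted p = 0.00682, and adjusted p = 0.380 with an estimated correlation). No rapid stress gene passed over all probe sets and 1 of 4 was higher adjusted over the list alone, with a list median of 0.59 (adjusted p = 0.0166, 0.0713 with the filter on dim probe sets, 0.127 without HA-RAP2.12 hypoxia replicate 3, and adjusted p = 0.380 with an estimated correlation). Single members of lists without a call also passed: AT2G41730 of the mitochondrial list was higher (1.83, SE 0.34), SBPASE was higher (0.34, SE 0.05), MCCB of the starvation list was lower (-0.51, SE 0.13) and RTE1 was lower (-0.35, SE 0.07). On the fermentation list PDC2 was lower, as above, and ACS was higher (0.32, SE 0.08, adjusted p = 0.0486), a call lost without any one of the 6 arrays compared. The root marker PYK10 stood at 6.86 ± 1.57 (n = 3) against 8.66 ± 0.09 (n = 3) in wild type (-1.80, SE 0.91, adjusted p = 0.368), with the lowest array, replicate 1, at 5.10, and AT4G11290 stayed at the floor. In total 476 probe sets were higher and 587 lower. That count of 1063 ranged from 411, without HA-RAP2.12 hypoxia replicate 3, to 1657, without amiRAP2.2-12 hypoxia replicate 2, and was 3926 with arrayWeights.

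In air, few probe sets of amiRAP2.2-12 rosettes passed the threshold against wild type. Some genes differed by large amounts without passing, and 3 are given after their values were seen. AT2G38240 stood at 8.63 ± 3.45 against 3.01 ± 0.05, petL at 8.19 ± 0.37 against 6.25 ± 0.36 and OSM34 at 2.68 ± 0.61 against 5.81 ± 0.49 (n = 3 each). The only named gene past the threshold was AT3G02930, at 3.26 ± 0.07 (n = 3) against 2.57 ± 0.05 (n = 3), a difference of 0.69 (SE 0.08) near the floor. Its call was lost with the replicate number as a block, with only the arrays compared and without wild type hypoxia replicate 1 or 2 (0.69 in each case), and without wild type air replicate 3 (0.68). The other 2 probe sets past it had no gene name and differed by 0.34 (SE 0.04, from a wild type level at the floor) and -0.89 (SE 0.11), and are given after their values were seen. No member of the low-oxygen list passed by either count, the list median was -0.03 (adjusted p = 0.214), and HRA1 differed by 0.10 (SE 0.33). None of the 9 lists tested gave a call in the main fit. In limma, 3 probe sets passed the adjusted threshold and 1768 had an unadjusted p under 0.05. The count of 3 was 378 without amiRAP2.2-12 air replicate 3, 209 with arrayWeights, 56 without the 4 arrays that deviated together, 38 with the filter on dim probe sets and 21 after median centring. It was 0 with the replicate number as a block and without wild type hypoxia replicate 1 or 2, and 1 without wild type air replicate 3 or wild type hypoxia replicate 3. The low-oxygen list passed as lower when only the arrays compared were fitted (adjusted p = 0.0220) and with arrayWeights (adjusted p = 0.0392).

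Under hypoxia, amiRAP2.2-12 held lower levels of low-oxygen genes than wild type, with a wide spread between its arrays. OSM34 was lower by the largest amount among named genes, at 2.86 ± 0.81 (n = 3) against 8.15 ± 0.13 (n = 3), a difference of -5.29 (SE 0.72), followed by AT1G53540 (-3.21, SE 0.72), AT5G24240 (-2.74, SE 0.23, at the floor in amiRAP2.2-12), AT1G26390 (-2.62, SE 0.30, at the floor in amiRAP2.2-12) and AT5G26200 (-2.61, SE 0.54). The SE pools the spread of all groups, and amiRAP2.2-12 under hypoxia varied more for AT1G53540 (3.59 ± 2.14) and AT5G26200 (7.54 ± 1.51, n = 3 each). AT3G04210 (2.18, SE 0.32), EXO (2.03, SE 0.37), LHCB4.3, a light-harvesting protein gene (1.88, SE 0.20), and the chloroplast-encoded psbT (2.03, SE 0.36) and petL (1.96, SE 0.40), subunits of photosystem II and of the cytochrome b6f complex, were higher. On the low-oxygen list 3 of 27 members were lower over all probe sets, AT5G26200, PDC2 (-1.49, SE 0.30) and AT1G74940 (-1.01, SE 0.19), and 20 adjusted over the list alone. The list mean was 9.13 ± 1.07 (n = 3) against 10.57 ± 0.03 (n = 3) in wild type, and the median difference was -1.30 (adjusted p = 2.85e-20, and adjusted p = 0.140 with an estimated correlation). HRA1 differed by -1.30 (SE 0.33) without passing (adjusted p = 0.0799). The array with the lowest list mean, replicate 2, stood apart on the second principal component, at -47.4 where the other 17 arrays lay between -13.9 and 19.8. The ribosomal protein gene AT5G60670 was at 9.57 on it, against 11.52 and 11.29 on replicates 1 and 3, and AT5G27850 at 12.10 against 13.39 and 13.22. The root marker PYK10 was at 3.85 on it, against 8.21 and 6.76, with a group difference from wild type of -2.38 (SE 0.91) that passed adjusted over its list alone but not over all probe sets (adjusted p = 0.274). Without replicate 2 the low-oxygen list median was -1.02 and the PYK10 difference -1.17.

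Heat shock genes were lower as a list (median -0.43, adjusted p = 0.0305), with 1 of 6 past the threshold and 2 adjusted over the list alone. Mitochondrial dysfunction genes were higher as a list (median 0.24, adjusted p = 0.0245), with 0 of 5 past the threshold and 3 adjusted over the list alone, among which AT2G41730 stood at 1.02 (SE 0.34) and NDB2 at 0.76 (SE 0.29). Photosynthesis genes were higher as a list (median 0.12, adjusted p = 0.0206), with SBPASE (0.28, SE 0.05) past the threshold and 2 of 5 adjusted over the list alone. With an estimated correlation these calls had adjusted p = 0.232, adjusted p = 0.169 and adjusted p = 0.226, and after median centring all 3 lists had adjusted p = 0.0677. The heat shock median was -0.00176 without amiRAP2.2-12 hypoxia replicate 2 (adjusted p = 0.196) and -1.17 with the filter on dim probe sets (0.0891). Its call was also lost without wild type hypoxia replicate 3 (a median of -0.60), without amiRAP2.2-12 hypoxia replicate 3 (-0.31, 0.117) and with only the arrays compared (0.190). The mitochondrial call was lost without wild type hypoxia replicate 3 (0.0671) or amiRAP2.2-12 hypoxia replicate 3 (0.16, adjusted p = 0.117), with the filter (0.128), with only the arrays compared (0.0701) and without probe sets ending in _s_at or _x_at (0.118). The photosynthesis call was lost without wild type hypoxia replicate 3 (0.0671) or amiRAP2.2-12 hypoxia replicate 2 (a median of 0.0709, adjusted p = 0.0896), with the filter (0.128) and with arrayWeights (0.167). In total 138 probe sets were higher and 185 lower, with 42.7% higher, or 53.2% higher after median centring. The count of 323 ranged from 105, without wild type hypoxia replicate 3, to 1021, without amiRAP2.2-12 hypoxia replicate 1, and was 10 when only the 6 arrays compared were fitted and 2400 with arrayWeights.

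The interaction compared each line's hypoxia response with that of wild type. For HA-RAP2.12 the response of several low-oxygen genes was smaller: AT4G10270 (-5.50, SE 0.52), AT5G66985 (-4.60, SE 0.82, at the floor in wild type air), AT1G33055 (-3.64, SE 0.34) and HRA1 (-2.73, SE 0.47). Outside that list, AT5G01740 (-3.57, SE 0.57) and AT1G26390 (-2.89, SE 0.42) also responded less. The response was higher for AT4G29780 (6.29, SE 0.89), AT1G78410 (4.90, SE 0.57), AT2G32030 (4.84, SE 0.66), B120 (4.73, SE 0.76) and AT3G01830 (4.53, SE 0.95, at the floor in HA-RAP2.12 air and wild type hypoxia). AT4G29780 fell in wild type from 9.18 ± 0.11 to 4.95 ± 0.16 (n = 3 each) and stood at 5.53 ± 0.31 in air and 7.59 ± 1.55 under hypoxia in HA-RAP2.12 (n = 3 each). Of the low-oxygen list, 5 members had a lower response and 1, AT1G72940 (1.44, SE 0.24), a higher one, and adjusted over the list alone 12 and 1. The list median was -1.59 (adjusted p = 1.11e-13, and adjusted p = 0.182 with an estimated correlation), where the lines differed by 0.56 in air and by -0.48 under hypoxia.

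Rapid stress genes responded more in HA-RAP2.12 (median 1.16, adjusted p = 0.000818, and adjusted p = 0.182 with an estimated correlation), with STZ (2.97, SE 0.56) past the threshold and 2 of 4 adjusted over the list alone. Heat shock genes responded less (median -0.88, adjusted p = 0.0337, 0.0634 after quantile normalization, and adjusted p = 0.252 with an estimated correlation), with 0 of 6 past the threshold and 1 adjusted over the list alone, AT1G53540 standing at -4.44 (SE 1.01, at the floor in all groups compared but wild type hypoxia). That call was lost without wild type air replicate 2 (0.0552) or 3 (0.0571), wild type hypoxia replicate 3 (0.0926), HA-RAP2.12 air replicate 1 (0.0525) or 3 (0.0740) or HA-RAP2.12 hypoxia replicate 3 (0.0508). Photosynthesis genes gave a median of 0.08 (adjusted p = 0.0337, 0.0962 after quantile normalization, 0.116 after median centring, 0.287 with the filter on dim probe sets, and adjusted p = 0.252 with an estimated correlation). None of the 5 passed the threshold, and 1 did adjusted over the list alone. Without wild type air replicate 1 the median was 0.0487 (adjusted p = 0.0824), and the call was also lost without wild type air replicate 2 (0.0552), wild type hypoxia replicate 3 (0.104) or HA-RAP2.12 air replicate 1 (0.0525) or 3 (0.0740). AT2G41730 of the mitochondrial list responded more (2.33, SE 0.48). In total 266 probe sets had a higher and 103 a lower response, and the count of 369 ranged from 201, without wild type air replicate 1, to 778, without amiRAP2.2-12 hypoxia replicate 2, and was 997 when only the 12 arrays compared were fitted.

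For amiRAP2.2-12, 40 probe sets responded differently from wild type, 18 with a higher and 22 with a lower value (45% higher, or 61.2% after median centring). AT3G04210 (2.58, SE 0.45), AT4G36550 (1.76, SE 0.30), AT2G10940 (1.70, SE 0.28), AT2G41090 (1.35, SE 0.20) and AT2G42040 (1.00, SE 0.17) were higher. AT5G24240 (-2.74, SE 0.32, off the floor only in wild type hypoxia among the 4 groups compared), AT1G26390 (-2.56, SE 0.42, at the floor in both amiRAP2.2-12 groups), AT1G02460 (-1.75, SE 0.29), AR791 (-1.13, SE 0.15) and AT1G73390 (-1.09, SE 0.17) were lower. No member of the low-oxygen list passed by either count, with HRA1 at -1.39 (SE 0.47) and AT4G10270 at -1.47 (SE 0.52), while the list median was -1.24 (adjusted p = 6.86e-11, and adjusted p = 0.242 with an estimated correlation). Photosynthesis genes gave a median of 0.20 (adjusted p = 0.00519, 0.114 after quantile normalization, 0.0708 after median centring, 0.110 with the filter on dim probe sets, 0.0570 without amiRAP2.2-12 hypoxia replicate 2, and adjusted p = 0.242 with an estimated correlation). None of the 5 passed the threshold, and 2 did adjusted over the list alone. The count of 40 was 0 without wild type air replicate 3, 394 without amiRAP2.2-12 hypoxia replicate 1 and 326 without amiRAP2.2-12 air replicate 3, and 8 when only the 12 arrays compared were fitted.

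**Figure D3:**
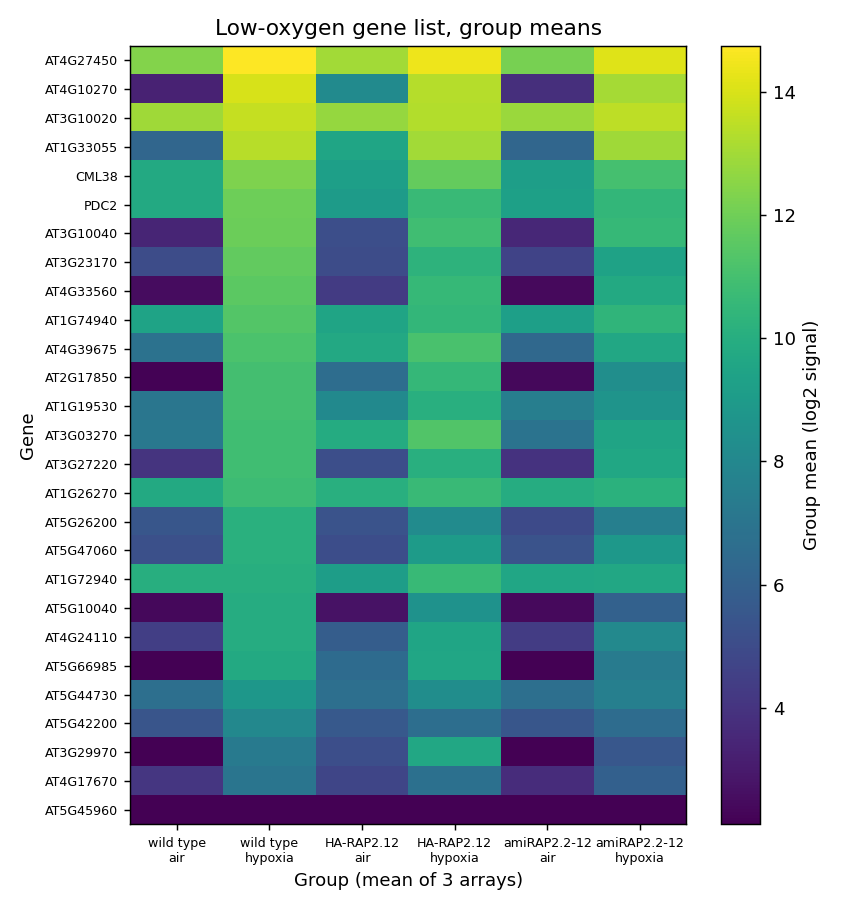
Group means (colour, log2 signal) of the 27 measured low-oxygen genes (rows) in the 6 groups (columns, 3 arrays each). AT4G10270 stood at 3.33 in wild type air, 8.18 in HA-RAP2.12 air and 14.00 in wild type hypoxia.

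Hypoxia-responsive probe sets chosen in the genotype left out of each test gave a further comparison of the lines. Sets chosen in amiRAP2.2-12 held 167 raised and 211 lowered probe sets. Against wild type, HA-RAP2.12 differed over the raised set by a median of -0.21 in air (adjusted p = 1.54e-09) and -0.34 under hypoxia (1.95e-10), and over the lowered set by 0.21 (4.17e-15) and 0.19 (5.05e-09). Without amiRAP2.2-12 hypoxia replicate 1 the calls in air were lost (-0.0889, adjusted p = 0.911, and 0.0152, adjusted p = 0.978), as was that of the raised set without amiRAP2.2-12 air replicate 1 (-0.18, 0.0613) and that of the lowered set without amiRAP2.2-12 hypoxia replicate 3 (0.12, 0.171). The interaction medians were -0.04 for the raised set (0.228) and -0.06 for the lowered set (0.735), and neither passed in the main fit. With trend and robust options the raised set passed as lower (-0.11, adjusted p = 0.0197) and the lowered set as higher (0.73, 0.0197). At a log2 limit of 2 the raised set also passed as lower (-0.12, 0.0151). The raised set passed as lower without HA-RAP2.12 air replicate 3 (-0.12, 0.0324), HA-RAP2.12 hypoxia replicate 1 (-0.16, 0.00173), amiRAP2.2-12 air replicate 1 (-0.39, 0.00125) or amiRAP2.2-12 hypoxia replicate 1 (-0.56, 2.61e-10) or 3 (-0.42, 0.00723). The lowered set passed as higher without amiRAP2.2-12 hypoxia replicate 1 (0.36, 0.000508), 2 (0.21, 0.00146) or 3 (0.68, 0.00723). Sets chosen in HA-RAP2.12 held 792 raised and 648 lowered probe sets. Over the raised set amiRAP2.2-12 differed from wild type by -0.13 in air (4.10e-07) and -0.12 under hypoxia (3.08e-05), with an interaction of -0.00452 (0.803, and -0.16 with adjusted p = 0.0121 without amiRAP2.2-12 hypoxia replicate 2). Over the lowered set it differed by 0.05 in air (0.0291) and 0.24 under hypoxia (1.31e-19), with an interaction of 0.20 (5.06e-09). The call in air over the lowered set was lost without wild type air replicate 3 (0.0460, adjusted p = 0.118), HA-RAP2.12 hypoxia replicate 1 (0.0271, 0.167), 2 (0.0340, 0.0752) or 3 (0.0302, 0.142) or amiRAP2.2-12 air replicate 2 (-0.0124, 0.647). With an estimated correlation, only the lowered set chosen in HA-RAP2.12 kept a call among these 12 tests, under hypoxia (adjusted p = 0.00572) and for the interaction (adjusted p = 0.0493).

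Calls in these fits were set against the response of the left-out genotype at the adjusted p alone. Of 152 probe sets higher in HA-RAP2.12 than in wild type in air, 10 were among those raised by hypoxia in amiRAP2.2-12, where independent lists would share 2.04, and 22 among those lowered, against 2.25. Of 311 lower, 19 were among the raised (4.18) and 2 among the lowered (4.59). Of 965 probe sets lower in HA-RAP2.12 than in wild type under hypoxia, 72 were among those raised by hypoxia in amiRAP2.2-12, where independent lists would share 12.98, and 6 were among those lowered, against 14.3. Of 984 higher, 7 were among the raised (13.2 for independent lists) and 48 among the lowered (14.5). Of 100 probe sets lower in amiRAP2.2-12 than in wild type under hypoxia, 37 were among those raised by hypoxia in HA-RAP2.12 (7.87) and 1 among those lowered (7.08). Of 46 higher, 26 were among the lowered (3.26) and 0 among the raised (3.62). These overlaps were not given a p-value.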

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

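Of the tests in this part, the scores and positions for a wrong label, the tests for a ceiling and the sets of genes sharing a symbol prefix were chosen only after the result was seen. Each result in the next 2 paragraphs was picked out by a test of the difference between a transgenic line's hypoxia response and that of wild type.

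For HA-RAP2.12 this difference passed for 369 probe sets. Low-oxygen genes responded less: AT4G10270 (-5.50), AT5G66985 (-4.60), AT1G33055 (-3.64), HRA1 (AT3G10040, -2.73) and the list median (-1.59), while AT1G72940 of that list responded more (1.44). AT4G29780 (6.29), AT1G78410 (4.90), AT2G32030 (4.84), B120 (4.73), AT3G01830 (4.53), STZ (2.97) and AT2G41730 (2.33) responded more, and AT5G01740 (-3.57) and AT1G26390 (-2.89) less. By list and family, rapid stress genes (1.16), photosynthesis genes (0.0762), PUB genes (1.35) and chloroplast-encoded genes (0.33) had higher medians, and heat shock genes a lower one (-0.88). With an estimated correlation every one of these calls was lost, with adjusted p = 0.182 for rapid stress and low-oxygen genes, 0.252 for photosynthesis and heat shock genes and 0.932 for PUB and chloroplast-encoded genes. The chloroplast-encoded call was lost without wild type hypoxia replicate 2 (0.18, adjusted p = 0.566) and without HA-RAP2.12 air replicate 2 (0.27, adjusted p = 0.0915).

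For amiRAP2.2-12 the difference passed for 40 probe sets, among them AT3G04210 (2.58), AT4G36550 (1.76), AT2G10940 (1.70), AT2G41090 (1.35) and AT2G42040 (0.998) with a higher response, and AT5G24240 (-2.74), AT1G26390 (-2.56), AT1G02460 (-1.75), AR791 (-1.13) and AT1G73390 (-1.09) with a lower one. The medians were -1.24 for the low-oxygen list, 0.20 for photosynthesis genes, 0.201 for probe sets lowered by hypoxia in HA-RAP2.12 and 0.33 for chloroplast-encoded genes. With an estimated correlation the lowered set kept its call (adjusted p = 0.0493), and the low-oxygen list (0.242), photosynthesis genes (0.242) and chloroplast-encoded genes (0.973) lost theirs. The chloroplast-encoded call was lost without wild type hypoxia replicate 2 (0.16, adjusted p = 0.217), without amiRAP2.2-12 hypoxia replicate 1 (0.17, adjusted p = 0.515) and after median centring (0.40, adjusted p = 0.175).

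The first pattern weighed is the spread among amiRAP2.2-12 hypoxia arrays, where the low-oxygen list mean of replicate 1 (10.36) lay near that of wild type (10.57) and the lowest array at 8.42. A weaker oxygen shortage in replicates 2 and 3 is argued against, because 648 probe sets lowered by hypoxia in HA-RAP2.12 fell there by at least 0.933 of their fall in replicate 1, above the limit of 0.8. A wild type array that varies like the 3 wild type hypoxia arrays is argued against: over 50 probe sets outside the low-oxygen list, chosen without replicate 1 to separate replicates 2 and 3 from wild type, replicate 1 lay at 0.361 or more of the way to them, above the limit of 0.106, and each wild type array left out of the choice at 0.0573 or less. The HA-RAP2.12 hypoxia arrays lay at 0.575 to 0.780 on these probe sets. The position of replicate 1 (up to 0.402) therefore does not mark it as amiRAP2.2-12, and it lay nearer to wild type than they did. A wild type array handled with the transgenic ones stays open, because over 50 probe sets separating replicates 2 and 3 from both other genotypes replicate 1 lay at 0.308 or more and left-out HA-RAP2.12 arrays at up to 0.323 (limit 0.769), though left-out wild type arrays reached only 0.0405 and all lay below replicate 1 within each choice, and a knockdown of unequal strength may also underlie the spread but was not tested. Scores from 50 probe sets chosen in air do not decide: the score separating the line from both others gave 0.0947 (highest wild type hypoxia array 0.0725, highest HA-RAP2.12 hypoxia array 0.0971, limit 0.354), and an earlier one, from wild type alone, gave 0.422 but was set aside because replicate 2 scored 0.0297 and HA-RAP2.12 air arrays 0.140, 0.614 and 0.495.

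The second pattern is that both lines differed from wild type under hypoxia in the same direction, with 65 probe sets higher and 102 lower in both, against 2.89 and 4.77 for independent lists. Chance values of the wild type arrays that both comparisons share, if independent between probe sets, are argued against as the whole cause. The covariance of the differences was 0.0775, and the highest of 100 simulated draws gave 0.0221. The correlation was 0.609, against a mean of 0.501 and a highest value of 0.5515 in the draws. Signs were the same in 70.9% of the brighter probe sets, against a mean of 66.6% and a highest value of 67.6%. Without any group difference, the draws still gave much of this agreement in direction from the shared arrays alone. The draws held no deviations that run through many probe sets of an array, so their range may be too narrow for chance of that kind. A shift of all wild type from all transgenic arrays at both oxygen levels is argued against as the whole cause, because the lower of the correlations between one line in air and the other under hypoxia was -0.187 (-0.0990 by rank), where such a shift needs both to reach 0.3. The other was 0.0460, and 0.125 by rank, which is above the limit of 0.1 that was set for both, so a smaller shift of this kind is not excluded. A technical shift confined to the wild type hypoxia arrays stays open, and a shared response of both lines is a hypothesis that may also account for the values. HA-RAP2.12 hypoxia replicate 1 and amiRAP2.2-12 hypoxia replicate 2 also deviated together from their group means (r = 0.634). The part of these arrays in the pattern was not tested.

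The third pattern is the smaller low-oxygen response of HA-RAP2.12. A ceiling of the signal is argued against for the part seen under hypoxia, because the lowest wild type array lay 0.411 above the highest HA-RAP2.12 array in the list mean, where the larger range within a group was 0.130. For the part from the higher start in air, over the 20 members higher in HA-RAP2.12 in air (median 1.25), the lowest wild type hypoxia array lay 0.304 above the highest HA-RAP2.12 array (larger range 0.126). This cannot decide, because the mean also takes in members barely higher in air, such as AT3G23170 (0.04 in air, -1.44 under hypoxia). Some members far higher in air came close to wild type under hypoxia, as AT5G66985 (4.43, then -0.17) and AT4G39675 (2.87, then -0.08). AT3G29970 stayed higher (3.02, then 2.41). Of these members, 17 were lower than wild type under hypoxia and 3 were not, among them AT5G45960 at the floor. Of the whole list, 22 members stood under log2 12 in wild type hypoxia, where the highest signal of each array was at least 15.83. Their median interaction was -1.65, against -0.909 for the 5 members at or over 12. For those 22 this argues against a ceiling common to all probe sets, but not against a ceiling of single probe sets. The altered RAP2.12 itself stays open as a cause and was not tested further.

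Other splits of the arrays were fitted for each comparison. For comparisons of 3 against 3 arrays, 10 splits are too few for a share under 0.05, and the following gives the number of splits with a result as large (the real one included), the real value and the highest other. Counts of probe sets: wild type response 1, 4951 and 1; HA-RAP2.12 response 1, 4404 and 2; amiRAP2.2-12 response 1, 3711 and 83; HA-RAP2.12 against wild type in air 1, 122 and 2, and under hypoxia 1, 1063 and 6; amiRAP2.2-12 against wild type in air 1, 3 and 2, and under hypoxia 1, 323 and 5. Sizes of the low-oxygen list median, in the same order: 1, 4.30 and 1.53; 1, 2.53 and 1.08; 1, 2.60 and 1.69; 1, 0.564 and 0.275; 1, 0.478 and 0.263; 6, 0.0272 and 0.129; 1, 1.298 and 1.275. Sizes for the sets raised, then lowered, by hypoxia in the genotype left out: HA-RAP2.12 in air 1, 0.209 and 0.180, then 1, 0.214 and 0.157; under hypoxia 1, 0.340 and 0.248, then 1, 0.185 and 0.122; amiRAP2.2-12 in air 1, 0.126 and 0.0849, then 5, 0.0519 and 0.0725; under hypoxia 4, 0.115 and 0.236, then 1, 0.235 and 0.109.

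For the interactions 100 splits were drawn. Under 0.05 of the splits were as large for the HA-RAP2.12 count (2 splits as large, real value 369, highest other 572) and its low-oxygen list (1 split, 1.59 and 1.14). The same held for the amiRAP2.2-12 count (1 split, 40 and 27) and its set lowered in HA-RAP2.12 (4 splits, 0.201 and 0.353). These shares were not adjusted for the number of results, so they do not exclude chance. The amiRAP2.2-12 count was also 0 without wild type air replicate 3. The split with 572 kept genotypes whole and exchanged them at 1 oxygen level, and the next highest gave 150. That split measures the genotype difference over both oxygen levels together, so it is not a chance split. Splits that mixed genotypes within an oxygen level also broke up any genotype difference common to both levels. The shares therefore do not test the interaction apart from such a difference. The share was above 0.05 for the amiRAP2.2-12 low-oxygen list (17 splits, 1.24 and 1.50) and its raised set (97 splits, 0.00452 and 0.337). It was also above 0.05 for the raised (83 splits, 0.0393 and 0.531) and lowered sets (71 splits, 0.0629 and 0.440) for HA-RAP2.12.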

How the results depend on the processing

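Leaving out 4 arrays that deviated together (HA-RAP2.12 air and hypoxia replicate 1, amiRAP2.2-12 air and hypoxia replicate 2) and the limit for the floor were chosen after the data were seen, as tests of dependence on those arrays and values. In all, 566 results were refitted under 32 settings, 18 of which left out a single array. The cause was not tested for any change below, except that a limit on the log2 change keeps fewer probe sets.

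The 9 low-oxygen list results kept direction and side of the threshold in all 162 fits without a single array and in 89 of the other fits. The 8 calls lost were those with an estimated correlation, at unchanged medians of 4.30, 2.53 and 2.60 (responses of wild type, HA-RAP2.12 and amiRAP2.2-12), 0.56 and -0.48 (HA-RAP2.12 in air and under hypoxia), -1.30 (amiRAP2.2-12 under hypoxia), -1.59 and -1.24 (interactions). The 2 gained were amiRAP2.2-12 in air with only the arrays compared (-0.0272) and with arrayWeights (-0.0751). Named genes counted as unchanged in 3470 fits, with 103 calls lost, 100 gained and no called gene reversed, and in 7935 without a single array, with 357 lost and 60 gained. Over all results, 358 changes of sign with neither value past the threshold also counted as unchanged, none of them for the low-oxygen list.

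Counts moved by over 1.5 times as follows. A log2 change of at least 1 gave 1608, 1664 and 1256 for the responses, 62 and 304 for HA-RAP2.12 in air and under hypoxia, 0 and 106 for amiRAP2.2-12, and 20 for its interaction. With only the arrays compared, the amiRAP2.2-12 response gave 642, amiRAP2.2-12 under hypoxia 10, and the HA-RAP2.12 and amiRAP2.2-12 interactions 997 and 8. With arrayWeights, HA-RAP2.12 gave 700 in air and 3926 under hypoxia, amiRAP2.2-12 209 and 2400, and the interactions 1393 and 735. The filter on dim probe sets gave 199 for HA-RAP2.12 in air, 38 and 516 for amiRAP2.2-12 in air and under hypoxia, and 559 and 63 for the interactions. Median centring gave 21 for amiRAP2.2-12 in air. Without the 4 arrays, HA-RAP2.12 in air gave 617, amiRAP2.2-12 in air 56 and its interaction 25.

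With the replicate number as a block (limma), HA-RAP2.12 in air gave 75, amiRAP2.2-12 in air 0 (main count 3, with 1768 at an unadjusted p under 0.05) and the amiRAP2.2-12 interaction 15. Arrays sharing a number correlated above 0.1 in 2 of 3 pairs for each hypoxia response. For line comparisons 1, 0, 0 and 0 of 3 did. Pairing within a genotype stays open and untested.

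For sets raised or lowered in the genotype left out, calls were lost with an estimated correlation for HA-RAP2.12 in air (-0.21 raised, 0.21 lowered) and under hypoxia (-0.34, 0.19) and for amiRAP2.2-12 in air (-0.13, 0.0519) and under hypoxia (raised, -0.12). The raised set for HA-RAP2.12 in air lost its call with trend and robust options (-0.27, 15 probe sets) and without the 4 arrays (-0.35, 2 probe sets). For the HA-RAP2.12 interaction, the raised set gained a call with trend and robust options (-0.11) and at a log2 limit of 2 (-0.12), and the lowered set reversed with trend and robust options (0.73, 11 probe sets). The lowered set for amiRAP2.2-12 in air lost its call with the filter on dim probe sets (0.0609) and at adjusted p alone (0.0217). Without the 4 arrays it reversed but did not pass (-0.0430, camera adjusted p = 0.174). The raised set for the amiRAP2.2-12 interaction gained a call, as lower, with median centring (median 0.0655), arrayWeights (-0.14), adjusted p alone (-0.0632) and without the 4 arrays (-0.22). Ribosomal protein genes for amiRAP2.2-12 under hypoxia reversed without the 4 arrays and without amiRAP2.2-12 hypoxia replicate 2 (0.22 each), with a range of -0.32 to 0.22 without single arrays.

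Without single arrays the counts for the responses ran from 3904 to 5669 (wild type), 3323 to 5075 (HA-RAP2.12) and 2843 to 3648 (amiRAP2.2-12), and the list medians from 4.21 to 4.44, 2.38 to 2.67 and 1.84 to 3.13. List medians ran from 0.44 to 0.60 and -0.53 to -0.42 for HA-RAP2.12 in air and under hypoxia, -0.11 to 0 and -1.89 to -1.01 for amiRAP2.2-12, and -1.67 to -1.40 and -1.79 to -0.94 for the interactions. HA-RAP2.12 in air ran from 35 to 343: without wild type air replicates 1 to 3 40, 52 and 35, wild type hypoxia 65, 59 and 78, HA-RAP2.12 air 2 42, HA-RAP2.12 hypoxia 2 and 3 75 and 71, amiRAP2.2-12 air 2 81, amiRAP2.2-12 hypoxia 1 and 2 204 and 343. HA-RAP2.12 under hypoxia ran from 411 to 1657: wild type hypoxia 658, 540 and 509, HA-RAP2.12 hypoxia 2 and 3 669 and 411, amiRAP2.2-12 hypoxia 2 1657. AmiRAP2.2-12 in air ran from 0 to 378: wild type air 10, 10 and 1, wild type hypoxia 0, 0 and 1, HA-RAP2.12 air 1 and 3 10 and 5, HA-RAP2.12 hypoxia 5 each, amiRAP2.2-12 air 7, 19 and 378, amiRAP2.2-12 hypoxia 1 12. Under hypoxia it ran from 105 to 1021: wild type hypoxia 209, 149 and 105, amiRAP2.2-12 hypoxia 1 and 3 1021 and 136. The HA-RAP2.12 interaction ran from 201 to 778: wild type air 201, 231 and 225, wild type hypoxia 2 and 3 236 and 210, HA-RAP2.12 air 2 214, HA-RAP2.12 hypoxia 1 and 3 234 and 227, amiRAP2.2-12 hypoxia 1 and 2 684 and 778. The amiRAP2.2-12 interaction ran from 0 to 394: wild type air 15, 11 and 0, wild type hypoxia 1 and 3 26 and 22, HA-RAP2.12 air 1 and 3 26 and 24, HA-RAP2.12 hypoxia 20, 22 and 22, amiRAP2.2-12 air 10, 18 and 326, amiRAP2.2-12 hypoxia 1 394.

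For the raised, then lowered, sets the medians ran for HA-RAP2.12 from -0.61 to -0.0889 and 0.0152 to 0.29 in air (0.0152 without amiRAP2.2-12 hypoxia 1, reversed by its test without passing), -0.71 to -0.30 and 0.11 to 0.57 under hypoxia, and -0.56 to 0.0705 and -0.12 to 0.68 for the interaction (reversed without amiRAP2.2-12 hypoxia 1, 2 and 3, at 0.36, 0.21 and 0.68). For amiRAP2.2-12 they ran from -0.15 to -0.10 and -0.0124 to 0.10 in air (reversed without amiRAP2.2-12 air 2, -0.0124), -0.26 to -0.03 and 0.21 to 0.28 under hypoxia, and -0.16 to 0.0766 and 0.16 to 0.26 for the interaction.

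Several lists without a call gained one when single arrays were left out, and not all are given here. For HA-RAP2.12 in air these were abscisic acid and cold genes without wild type air 3 (adjusted p = 0.0377), HA-RAP2.12 air 2 (0.0385), HA-RAP2.12 hypoxia 2 (0.0445), amiRAP2.2-12 air 3 (0.0341) or amiRAP2.2-12 hypoxia 1 or 2 (0.0241, 0.0274), photosynthesis genes without wild type air 3 (0.0264) or HA-RAP2.12 air 2 (0.0450), and ribosomal genes without amiRAP2.2-12 hypoxia 2 (0.0117). For amiRAP2.2-12 in air they were rapid stress genes without amiRAP2.2-12 hypoxia 2 (0.0427) and abscisic acid and cold genes without amiRAP2.2-12 air 3 (0.0426). Without amiRAP2.2-12 hypoxia 1, its interaction gained heat shock (-1.10, 0.000912), mitochondrial (0.34, 0.00410) and fermentation genes (-0.37, 0.0399). Without amiRAP2.2-12 hypoxia 2, that line under hypoxia gained rapid stress (-0.47, 0.0337) and ribosomal genes (0.22, 0.00703).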

Other observations

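The sets of genes sharing a symbol prefix, and their tests under other scalings and without single arrays, were chosen after the data were seen. Of 32 such sets, chloroplast-encoded genes (69 probe sets) were higher than wild type under hypoxia in both lines, by a median of 0.47 in HA-RAP2.12 (adjusted p = 2.81e-10, and adjusted p = 0.629 with an estimated correlation; 0 members past the threshold in limma) and 0.36 in amiRAP2.2-12 (adjusted p = 2.14e-07, and adjusted p = 0.843 with an estimated correlation; 3 members). The directions held after quantile normalization (0.44 and 0.37) and median centring (0.45 and 0.40). Their mean was 9.86 ± 0.29 in wild type hypoxia against 10.21 ± 0.10 in wild type air, 10.45 ± 0.06 in HA-RAP2.12 hypoxia and 10.43 ± 0.48 in amiRAP2.2-12 hypoxia (n = 3 each). Without wild type hypoxia replicate 2 the differences were 0.26 (adjusted p = 0.000289) and 0.22 (adjusted p = 0.134), and without amiRAP2.2-12 hypoxia replicate 1 the latter was 0.21 (adjusted p = 0.0962).

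PUB genes, which encode U-box proteins (9 probe sets), were higher in HA-RAP2.12 than in wild type under hypoxia by a median of 0.68 (adjusted p = 0.0139, and adjusted p = 0.629 with an estimated correlation; 2 members past the threshold), but without HA-RAP2.12 hypoxia replicate 1 by 0.52 (adjusted p = 0.0831). Their mean went from 5.69 ± 0.05 in air to 5.43 ± 0.11 under hypoxia in wild type and from 5.30 ± 0.06 to 6.07 ± 0.23 in HA-RAP2.12 (n = 3 each). The interaction (1.35) passed under both scalings and without each single array, but not with an estimated correlation (adjusted p = 0.932). In the response to hypoxia, UGT genes (47 probe sets) held 13 that rose and 4 that fell in HA-RAP2.12 (adjusted p = 0.0369, and adjusted p = 0.593 with an estimated correlation), beside 13 and 5 in wild type (adjusted p = 0.0586) and 12 and 3 in amiRAP2.2-12 (adjusted p = 0.0550). Their mean went from 4.58 ± 0.06 to 5.22 ± 0.08 in HA-RAP2.12, from 4.70 ± 0.04 to 5.19 ± 0.02 in wild type and from 4.70 ± 0.06 to 5.09 ± 0.14 in amiRAP2.2-12 (n = 3 each). SEC genes (9 probe sets) were higher in HA-RAP2.12 than in wild type under hypoxia by 0.18 (adjusted p = 0.0218, and adjusted p = 0.629 with an estimated correlation).

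Probe sets without a gene name included some of the largest differences between lines, chosen after their values were seen. The most raised in HA-RAP2.12 in air stood at 12.06 there and at 2.33 in wild type air, 10.56 in wild type hypoxia, 12.19 in HA-RAP2.12 hypoxia and 7.38 in amiRAP2.2-12 hypoxia. The most lowered in HA-RAP2.12 under hypoxia stood at 3.21 there, 9.31 in wild type hypoxia and 4.37 in amiRAP2.2-12 hypoxia, and the most lowered in amiRAP2.2-12 under hypoxia at 4.41 there, 8.51 in wild type hypoxia and 6.07 in HA-RAP2.12 hypoxia. Which genes they measure is not given in the sources used here.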
